A study of Mus musculus with 6 samples.

How the data were processed

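Total RNA of thymocytes labelled double-negative, sorted by flow cytometry from mouse thymus, was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. There were 6 samples, 3 Toxf/f and 3 Toxf/fPdcd1Cre, grouped by the genotype in their labels. For each sample the authors deposited 1 table of 22298 genes with an estimated count and an FPKM value (fragments scaled to gene length and library size) per gene, per the file headers, with gene symbols and annotation terms. Per the submitters' processing notes the tools included fastp 0.18.0, HISAT2 and StringTie 1.3.1; their roles, the genome build, the annotation, the counting tool and any use of strand are not given in the sources used here. The deposited counts were expected counts: 8.81% to 9.84% of genes per library had a value that was not whole, and totals differed between libraries from 14245492 to 16199195.

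The files of Toxf/f replicates 1 and 2 were identical in every value. They were counted as 1 library, so that 5 distinct libraries entered the tests, 2 against 3, where the design fixed beforehand had 3 against 3. The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 14121; 3468 of the listed genes were at 0 in every library. Libraries were scaled by TMM (trimmed mean of M-values) and tested with edgeR 4.0.16 by its quasi-likelihood test in R 4.3.3, Toxf/fPdcd1Cre minus Toxf/f with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM on the TMM-scaled library sizes. Tox was also tested by an exact permutation of log2 values.

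Named genes were chosen by a rule. Tox and Pdcd1 were always named. Then came the 12 largest rises and 12 largest falls among genes past the threshold with library values that did not overlap between genotypes and a mean of at least 1 CPM, leaving out predicted genes, pseudogenes and V, D and J segments. From each list that was called or had at least 1 changed member up to 4 members with the smallest p were named, and from lists of other cell types and of quality the 2 members with the highest mean. The design, the rule, the alternatives and 37 gene lists were fixed before the data were examined, and 583 of the 608 distinct genes on them matched a gene in the files. Lists were tested on log2 CPM with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Terms of 10 to 300 tested genes were tested by one-sided Fisher's exact tests against 14036 tested genes with at least 1 term.

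Coordinates come from GENCODE M21 on GRCm38, matched by Ensembl identifier for 22255 of the 22298 genes, and may differ from the build behind the files. Of 113 named genes with a position, 14 overlap another listed gene. For genes with few counts, folds against a genotype at 0 are lower bounds from a floor of 3 counts over the group, and folds with 1 to 3 counts have an exact 95% binomial interval of the split of counts. Intervals and floors cover counting error only.

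The tests were checked on simulated counts with the real genes, means and library sizes. Variance followed only its fitted trend with mean level, and no library was set apart from its group. The changed genes had a mean of at least 1 CPM. With 200 of 14121 genes changed 2-fold the test recovered 64% and made 8 false calls; with 200 changed 4-fold it recovered 96.5% and made 6 false calls; with none changed it made 0 calls. Alternatives were DESeq2's size factors within edgeR (RLE), upper-quartile factors, no filter, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) for genes with at least 1 FPKM in 3 libraries, age as a covariate, the replicate number as a block, a log2 fold change of at least 1, leaving out Xist and chromosome Y genes, and leaving out each library. Xist was not used here. Some genes that the rule gave are not reported here. Figures were drawn with matplotlib.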

Results

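The series profiled messenger RNA of thymocytes labelled double-negative, a name for the immature T cell precursors of the thymus that carry neither CD4 nor CD8 on their surface, from C57BL/6 mice. Cells were sorted from Toxf/f mice, in which the gene Tox is flanked by recombination sites, and from Toxf/fPdcd1Cre mice, which carry in addition a Cre recombinase named for Pdcd1, the gene of the inhibitory receptor PD-1. Each genotype had 3 samples, replicates 1 and 2 from mice 3 weeks old and replicate 3 from mice 4 weeks old. The series' title and sample names speak of the whole double-negative population, while the protocol speaks of its second stage, DN2, and this difference stands unresolved here. The deposited files of Toxf/f replicates 1 and 2 held identical values and were counted as 1 sample. Values of its own for 1 of these 2 replicates were thus not available. This left 2 distinct Toxf/f libraries against 3 Toxf/fPdcd1Cre libraries. No label says which samples came from separate mice, so p-values measure only the spread between these libraries. Total estimated counts per library ranged from 14245492 to 16199195 over 22298 listed genes.

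Some genes show what RNA the libraries held. Transcripts of Rag1, Cd8a and Cd4 ranked 3, 26 and 105 among all genes by mean level. The ranks of Cd8a and Cd4 go against libraries of double-negative cells alone. The name is therefore used below only as the labels give it. Cd4 averaged 877 ± 45.5 CPM (counts scaled to library size; SD, n = 2) in Toxf/f and 859 ± 133 CPM (SD, n = 3) in Toxf/fPdcd1Cre libraries. Ccl25, a chemokine of thymic epithelium, averaged 667 ± 54.5 CPM (SD, n = 2) and 738 ± 39.2 CPM (SD, n = 3). Toxf/fPdcd1Cre replicate 1 stood apart in the chromosome Y gene Ddx3y, with 1 count against 843 to 1354 in the other 4 libraries. In a principal component analysis the first component held 50.7% of the variance, with Toxf/f at -25.4 and -40.2, Toxf/fPdcd1Cre replicate 1 at -8.19 and the remaining Toxf/fPdcd1Cre libraries at 35.8 and 37.9.

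The comparison of the genotypes asks how the transcriptome of the cells labelled double-negative differs when Tox, a DNA-binding factor of T cell development, is targeted. Tox itself fell to 14.5% of its Toxf/f level, from 113 ± 11.5 CPM (SD, n = 2) to 16.5 ± 2.69 CPM (SD, n = 3). The gene (ENSMUSG00000041272) lies on chromosome 4 from 6686353 to 6991557 in GRCm38, on the minus strand. The distinct Toxf/f libraries held 1896 and 1746 Tox counts and 31.1 and 27.5 FPKM, and the Toxf/fPdcd1Cre libraries held 281, 257 and 201 counts and 4.98, 4.01 and 3.34 FPKM. The log2 fold change was -2.78 ± 0.161 (SE), with an adjusted p of 6.72e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test over the 10 splits of the 5 libraries gave p = 0.1, the smallest value this design allows. The value covers the whole gene, including any exons outside the deleted part. Pdcd1, on chromosome 1 from 94038305 to 94052553, had 19 counts in the Toxf/f library shared by replicates 1 and 2 and 0 in the other 4 libraries, which was too low for the filter on counts, so it received no test.

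**Figure D1:**
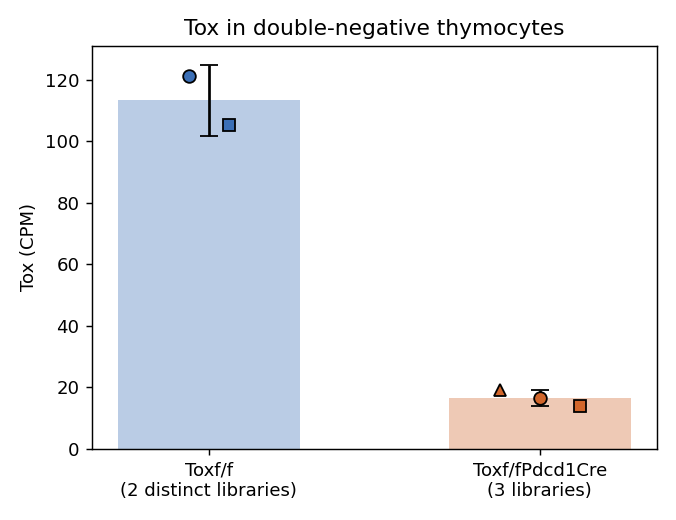
Tox level in CPM (vertical axis) for each distinct library (points), with the genotype mean (bars) and SD (error bars). The 2 Toxf/f libraries average 113 CPM and the 3 Toxf/fPdcd1Cre libraries average 16.5 CPM, without overlap.

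Across the transcriptome most of the genes that changed were lower in Toxf/fPdcd1Cre cells. Of 14121 genes tested, 232 changed, 213 lower and 19 higher. Class-switched immunoglobulin heavy chain genes, the light chain gene Igkc, the regulatory T cell factor Foxp3 and the homing receptor Ccr7 fell, while 4 of 9 tested killer cell lectin-like receptor (Klr) genes, the scavenger receptor Cd163l1 and the hormone-processing enzyme Pcsk1 rose. At an unadjusted p under 0.05 there were 1025 lower and 435 higher genes. All 232 had library values that did not overlap between genotypes, as did 3696 of the tested genes, where chance gives 20%. The 232 included 5 predicted genes and 11 immunoglobulin or T cell receptor V, D or J segments, all 11 lower. The count was 49 without the Toxf/f library of replicates 1 and 2, 31 without Toxf/f replicate 3, 606 without Toxf/fPdcd1Cre replicate 1 and 114 without Toxf/fPdcd1Cre replicate 3. Of 51 called genes that the naming rule gave besides Tox, 12 stayed past the threshold whichever of the 5 libraries was left out: Pcsk1, Akr1c13, Ighe, Igha, Ighg2b, Ighg2c, Jchain, Pla2g2d, Igkc, Gimap3, Ccr7 and Tnfrsf9.

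Class-switched immunoglobulin heavy chain genes were nearly absent from Toxf/fPdcd1Cre libraries. Their summed counts were 1660 and 1298 in the Toxf/f libraries and 12, 10 and 20 in the Toxf/fPdcd1Cre libraries. Igha, the constant region of IgA, fell from 33.9 ± 2.47 to 0.339 ± 0.243 CPM (log2 fold change -6.62 ± 0.325 SE, adjusted p = 3.19e-06, edgeR). This gene lies on chromosome 12 from 113254830 to 113260236. Ighg2b fell by 6.62, Ighg2c fell by 6.11 and Ighg3 fell by 5.72 on the log2 scale. Ighe had 159 counts in all in Toxf/f and 1 in Toxf/fPdcd1Cre libraries, a 221-fold lower level with a 95% counting interval of 39.2 to 8790, which became 144-fold without Toxf/fPdcd1Cre replicate 2 and at least 49.7-fold without replicate 1, where no count was left. Ighg1 had 251 and 3 counts, a 116-fold lower level with an interval of 39.4 to 568. Of the 251 counts 208 came from the library of Toxf/f replicates 1 and 2, and the fold was 38.7 without it, 199 without Toxf/f replicate 3 and 235 without Toxf/fPdcd1Cre replicate 1. The joining chain gene Jchain fell by 3.80 and the kappa light chain constant gene Igkc fell by 3.45. Ighm, the constant region of IgM, was at 665 ± 112 CPM in Toxf/f and 565 ± 67.1 CPM in Toxf/fPdcd1Cre libraries (adjusted p = 0.715, edgeR). Igll1, which encodes a part of the surrogate light chain of B cell precursors, rose from 0.343 ± 0.0587 to 2.24 ± 0.271 CPM (log2 fold change 2.68 ± 0.543). Heavy chain constant genes resemble one another and counting may split reads between them, so each single value is uncertain. The log2 fold changes of Igha and Ighg2b were -7.36 and -7.35 without Toxf/fPdcd1Cre replicate 3, that of Jchain was -4.57 without replicate 2, and that of Ighg3 was -6.99 without replicate 1 and -4.83 without the library of Toxf/f replicates 1 and 2. Without the library of Toxf/f replicates 1 and 2 the calls of Ighg1, Ighg3 and Igll1 ended (adjusted p = 0.0962, 0.114 and 0.216, edgeR), and Igll1 was also lost without Toxf/f replicate 3 (adjusted p = 0.349) and without Toxf/fPdcd1Cre replicate 2 or 3 (adjusted p = 0.0570 and 0.115).

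Some further genes stood among the largest falls. Foxp3 fell from 8.56 ± 1.69 to 0.264 ± 0.229 CPM, a log2 fold change of -4.96 ± 0.573 (adjusted p = 0.00127, edgeR), and was not called without Toxf/f replicate 3 (adjusted p = 0.0868). It overlaps Ccdc22 and Ppp1r3f on the opposite strand, which did not pass the test. The secreted phospholipase gene Pla2g2d fell by 3.62 on the log2 scale. Commd1b is annotated on chromosome 11 from 22834744 to 22982090, across the copper-handling gene Commd1. It had 141 counts in Toxf/f and 0 in all Toxf/fPdcd1Cre libraries. This is at least 65.4-fold lower against a floor of 3 counts over the group. The bound became 42.3-fold without the library of Toxf/f replicates 1 and 2 and 42.6-fold without Toxf/fPdcd1Cre replicate 2. Commd1b overlaps Commd1 and B3gnt2 on the same strand (log2 fold changes 0.28 and 0.175, adjusted p = 0.629 and 0.752, edgeR). Counting may split reads between these genes, and not all counts of Commd1b were whole numbers. The call of Commd1b ended without the library of Toxf/f replicates 1 and 2.

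The genes with the largest rises included receptors of natural killer and innate-like lymphocytes. Klrc2 rose from 0.185 ± 0.0798 to 1.63 ± 0.101 CPM and Klra5, a member of the Ly49 family, from 0.245 ± 0.165 to 1.97 ± 0.532 CPM. Klrb1c, which encodes NK1.1, rose 3.49-fold and Klrk1, which encodes NKG2D, rose 3.22-fold (log2 fold changes 1.80 ± 0.374 and 1.69 ± 0.292). Cd163l1 rose 10.2-fold, from 4.28 ± 1.46 to 43.6 ± 29.8 CPM, and 6.01-fold without Toxf/fPdcd1Cre replicate 1, which held 78.0 CPM against 27.4 and 25.4 CPM in the other libraries of its genotype. Trdc, the constant gene of the T cell receptor delta chain, rose 1.82-fold, from 143 ± 23.6 to 260 ± 57.2 CPM. Pcsk1 rose 10.6-fold (log2 fold change 3.40 ± 0.267, adjusted p = 0.000139, edgeR). The aldo-keto reductase genes Akr1c13 and Akr1c12, the matrix protein gene Chad and the adenylate cyclase gene Adcy1 also rose, with log2 fold changes of 1.77, 1.76, 2.97 and 1.11. Klr and Akr1c genes come in families of similar copies whose reads counting may split. Not all counts of Klrc2, Akr1c12 and Akr1c13 were whole numbers. Of these 11 genes, only Pcsk1 and Akr1c13 kept their call without either Toxf/f library in turn; for the other 9, adjusted p ranged from 0.115 (Cd163l1) to 0.381 (Chad and Klrb1c) without the library of replicates 1 and 2, and from 0.208 (Adcy1) to 0.588 (Trdc) without replicate 3. The log2 fold change of Klra5 was 3.86 without Toxf/f replicate 3, and that of Chad was 4.20 without that library, 2.34 without the library of replicates 1 and 2 and 2.39 without Toxf/fPdcd1Cre replicate 1. The other 5 tested Klr genes did not pass: Klrb1b at 2.53, Klra1 at 2.23, Klrb1f at 0.75, Klrc1 at 0.52 and Klrd1 at -0.19 (adjusted p = 0.0628, 0.262, 0.770, 0.850 and 0.954). Without Toxf/fPdcd1Cre replicate 1, the library with almost no chromosome Y reads, Klrc2, Klra5, Klrb1c, Klrk1, Cd163l1 and Trdc stayed past the threshold, with adjusted p from 0.00142 (Cd163l1) to 0.0421 (Trdc), while Chad did not (adjusted p = 0.0581). Klrc2 was also lost without Toxf/fPdcd1Cre replicate 2 (adjusted p = 0.0793), and Klrc2, Chad, Klra5 and Trdc without replicate 3 (adjusted p = 0.0983, 0.0721, 0.116 and 0.0666). Counting all alternatives to the processing, the call held in 8 of 16 for Klrc2 and for Klra5, 7 of 16 for Chad, 10 of 16 for Klrb1c, 12 of 16 for Akr1c12, 9 of 17 for Trdc and 13 of 17 for each of Klrk1, Adcy1 and Cd163l1, whose adjusted p reached 0.458 with limma-voom.

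**Figure D2:**
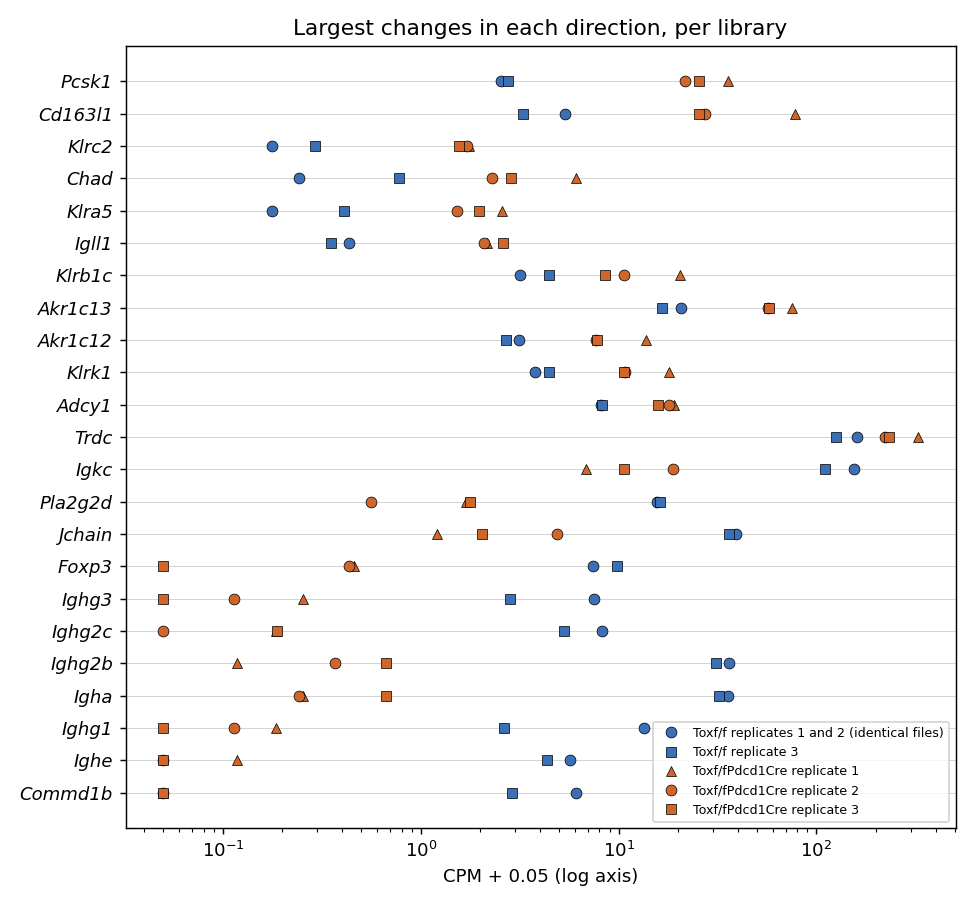
Level of the 12 genes with the largest rise and of 11 of the 12 with the largest fall (rows) in CPM plus 0.05, on a log axis, with 1 point per distinct library (blue Toxf/f, orange Toxf/fPdcd1Cre). Points of the genotypes do not overlap in any of these rows, and Commd1b sits at 0 CPM in all 3 Toxf/fPdcd1Cre libraries.

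Lists of genes by cell type and pathway were compared next. Of genes of mature single-positive T cells 10 of 18 tested members were lower, 0 higher, and 15 were lower adjusted over the list alone. The median over the list was -0.76 on the log2 scale and camera with its preset correlation gave an adjusted p of 3.22e-12, against an adjusted p = 0.470 with an estimated correlation, at which the list was not called. The chemokine receptor Ccr7, which guides cells to the medulla and lymph nodes, fell 4.56-fold (log2 fold change -2.19 ± 0.220, adjusted p = 0.000508, edgeR). The GTPase gene Gimap3 fell 3.99-fold and the transcription factor Klf2 fell 2.34-fold, and S1pr1, the receptor for thymic exit, fell 3.31-fold. Without Toxf/fPdcd1Cre replicate 1, 11 members were lower and the median was -0.94. Klf2 was not called without Toxf/f replicate 3 (adjusted p = 0.102), and S1pr1 was not called without that library or without the library of replicates 1 and 2 (adjusted p = 0.140 and 0.0556).

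Of genes induced by T cell receptor signals 6 of 17 tested members were lower, 0 higher and 11 lower adjusted over the list alone. The list had a median of -0.68 and a camera adjusted p of 1.76e-08, against an adjusted p = 0.384 with an estimated correlation. The co-stimulatory receptor Tnfrsf9 fell 5.02-fold (log2 fold change -2.33 ± 0.242, adjusted p = 0.000574, edgeR). The nuclear receptors Nr4a1 and Nr4a3 fell 2.27-fold and 2.25-fold, and the stress-response gene Gadd45b fell 2.74-fold. The list of immediate-early genes, which respond to stimulation and to tissue dissociation, had 16 of 16 fold changes below 0, of which Nr4a1 passed the test, with a camera adjusted p of 0.000132 and an adjusted p = 0.537 with an estimated correlation. Junb, at -0.50, and Egr1, at -0.39, did not pass (adjusted p = 0.154 and 0.221, edgeR). Nr4a1, Nr4a3 and Gadd45b lost their calls without the library of Toxf/f replicates 1 and 2 (adjusted p = 0.107, 0.0805 and 0.162) and without Toxf/f replicate 3 (adjusted p = 0.130, 0.224 and 0.326), and Gadd45b without Toxf/fPdcd1Cre replicate 3 (adjusted p = 0.0745).

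Of interferon-stimulated genes 7 of 26 tested members were lower, 0 higher and 18 lower adjusted over the list alone. The median was -0.72, and the camera adjusted p of 3.22e-12 stood against an adjusted p = 0.510 with an estimated correlation and an adjusted p = 0.146 by fry's directional test. The nucleic acid sensor Zbp1 fell 2.52-fold, the interferon regulatory factor Irf7 fell 2.43-fold and the guanylate-binding protein gene Gbp2 fell 1.63-fold. Without Toxf/fPdcd1Cre replicate 1, 18 members were lower. Each of these 3 genes lost its call without the library of Toxf/f replicates 1 and 2 (adjusted p = 0.126 to 0.280, edgeR) and without Toxf/f replicate 3 (adjusted p = 0.187 to 0.371). Without Toxf/fPdcd1Cre replicate 3 Irf7 and Gbp2 were not called (adjusted p = 0.05004 and 0.119).

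Among lists of other cell types those of dendritic cells and B cells were called, while the monocyte, mast cell, erythroid and thymic epithelial lists were not (camera adjusted p = 0.266, 0.522, 0.183 and 0.683). The mast cell list was called as lower without Toxf/fPdcd1Cre replicate 1 (adjusted p = 0.0193) and the erythroid list without replicate 2 (adjusted p = 0.0147). Among dendritic cell genes 4 of 20 were lower and 0 higher, with 12 lower adjusted over the list alone: the chemokine Ccl22 fell 7.02-fold, from 123 ± 8.33 to 17.6 ± 12.5 CPM (12.2-fold without Toxf/fPdcd1Cre replicate 1), the cytokine receptor Flt3 fell 2.08-fold, and H2-Eb1 and Cd74 of antigen presentation by MHC class II fell 1.87-fold and 1.67-fold. The dendritic cell list had a median of -0.57 and a camera adjusted p of 1.94e-07, and an adjusted p = 0.501 with an estimated correlation. The B cell list had 2 of 20 members lower (Igkc and Cd74) and 1 higher (Igll1), a median of -0.48 and a camera adjusted p of 0.0287, against an adjusted p = 0.537 with an estimated correlation, and it lost its call without Toxf/f replicate 3 (adjusted p = 0.475) or Toxf/fPdcd1Cre replicate 1 or 3 (adjusted p = 0.0713 and 0.0653). The call of the B cell list held in 4 of 13 alternatives, and was lost also with no low-count filter, a replicate block, age as a covariate or the identical files counted separately. Of 21 thymic epithelial and stromal genes 12 had fold changes above 0, with a median of 0.13 that became -0.14 without Toxf/fPdcd1Cre replicate 1, and 1 was lower (3 without that library), Krt14, a keratin of medullary epithelium, which fell 2.44-fold, while Aire, the regulator of self-antigens in that epithelium, stood at a log2 fold change of -1.47 ± 0.428 that did not pass (adjusted p = 0.158, edgeR). The chemokine gene Ccl5 of cytotoxic cells fell 3.60-fold (5.42-fold without Toxf/fPdcd1Cre replicate 1), and Ccr6, a chemokine receptor listed with gamma-delta T cell genes, fell 8.32-fold (4.63-fold without Toxf/f replicate 3). Of gamma-delta T cell genes 2 of 18 were higher (Cd163l1 and Trdc) and 1 lower (Ccr6), and of natural killer and cytotoxic genes 2 of 18 were higher (Klrk1 and Klrb1c) and 1 lower (Ccl5), with no call for either list (camera adjusted p = 0.320 and 0.692). Ccl22, Flt3, H2-Eb1, Cd74, Krt14 and Ccl5 lost their calls without the library of Toxf/f replicates 1 and 2 (adjusted p = 0.0715 to 0.169) and, with Ccr6, without Toxf/f replicate 3 (adjusted p = 0.102 to 0.458), Cd74 without Toxf/fPdcd1Cre replicate 2 (adjusted p = 0.0560), and Flt3, H2-Eb1, Cd74 and Krt14 without Toxf/fPdcd1Cre replicate 3 (adjusted p = 0.0650 to 0.132).

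Some receptor and survival genes were lower. Of cytokine receptor and signalling genes 4 of 26 were lower and 0 higher, among them the survival factor Bcl2, which fell 2.11-fold (log2 fold change -1.07 ± 0.134, adjusted p = 0.00240, edgeR), the interleukin receptor gene Il6ra, which fell 2.74-fold, and Il7r, which fell 1.68-fold. Of chemokine receptor and adhesion genes 4 of 18 were lower and 0 higher, including Ccr4, which fell 2.09-fold, and the adhesion receptor Cd44, which fell 1.59-fold. Of inhibitory receptor genes 1 of 13 was lower, Btla, which fell 1.83-fold. In the TOX family Tox was the 1 changed member of 4: Tox2 stood at -1.10 ± 0.379 (adjusted p = 0.269, edgeR), Tox3 at 0.13 and Tox4 at -0.01. These 4 lists had camera adjusted p of 0.00144, 0.00240, 0.00282 and 0.0209, and adjusted p = 0.470, 0.470, 0.537 and 0.501 with an estimated correlation. The TOX family list lost its call without Toxf/f replicate 3 (adjusted p = 0.0912) or Toxf/fPdcd1Cre replicate 1 (adjusted p = 0.188). Bcl2, Il7r, Ccr4, Cd44 and Btla lost their calls without the library of Toxf/f replicates 1 and 2 (adjusted p = 0.0552 to 0.305) and, with Il6ra, without Toxf/f replicate 3 (adjusted p = 0.0587 to 0.464), Il7r and Cd44 without Toxf/fPdcd1Cre replicate 2 (adjusted p = 0.0934 and 0.103), and Il7r, Ccr4, Cd44 and Btla without Toxf/fPdcd1Cre replicate 3 (adjusted p = 0.05004 to 0.175).

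Lists of cell division and of ribosomal proteins lay slightly higher in Toxf/fPdcd1Cre cells, with no single member past the threshold and no call of a list at an estimated correlation. All 25 S phase genes and all 25 G2/M genes had fold changes above 0, with medians of 0.28 and 0.27, and 36 of 40 cytosolic ribosomal protein genes did, with a median of 0.12. The replication enzyme Rrm1 stood at 0.41 ± 0.141 (adjusted p = 0.274, edgeR) and the mitotic activator Cdc20 at 0.43 ± 0.133 (adjusted p = 0.188). Camera gave adjusted p of 1.56e-06, 1.07e-06 and 0.00586 for the S phase, G2/M and ribosomal lists, against adjusted p = 0.592, 0.548 and 0.798 with an estimated correlation. Without Toxf/f replicate 3 the S phase and ribosomal lists were not called (adjusted p = 0.0649 and 0.475), nor the ribosomal list without Toxf/fPdcd1Cre replicate 2 (adjusted p = 0.193). In all, camera with the preset correlation called 13 of 37 lists, 10 lower and 3 higher. The TOX family list among the 10 holds Tox, the targeted gene, so its call is no independent finding. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.384). Fry's directional test called 0 and fry's test for change in either direction called 10. These 10 were not the lists that camera called lower. They included the natural killer, mast cell and apoptosis regulator lists, which camera did not call. They left out the interferon, dendritic cell, immediate-early, S phase, G2/M and ribosomal lists.

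**Figure D3:**
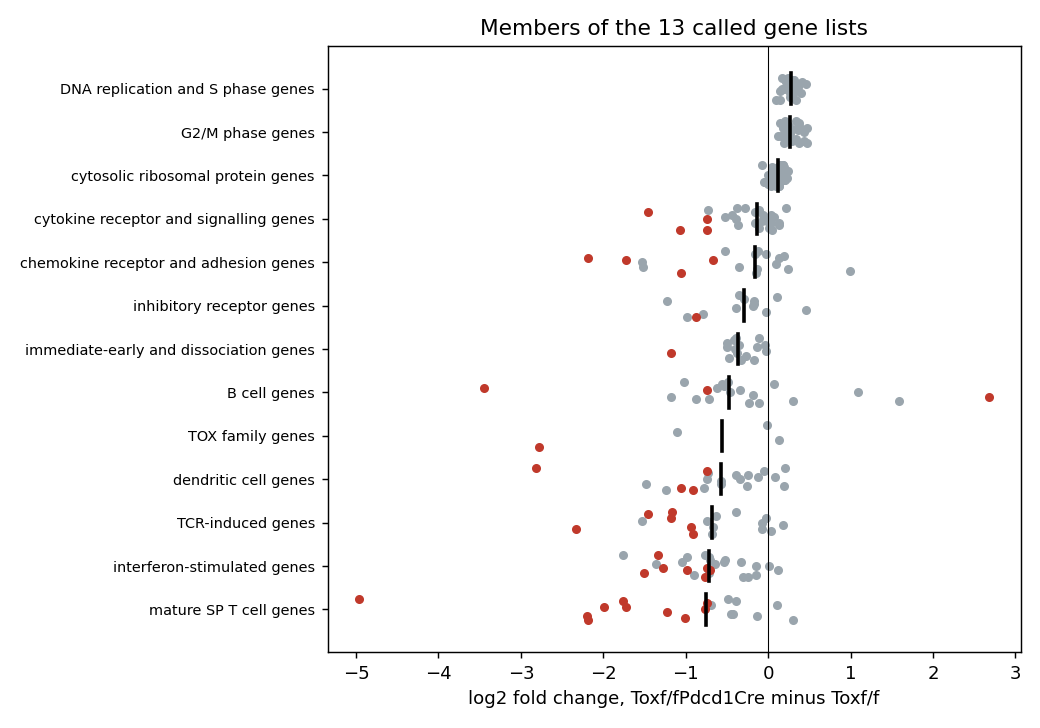
Log2 fold change, Toxf/fPdcd1Cre minus Toxf/f (horizontal axis), of each tested member of the 13 gene lists called by camera (rows), with members past the threshold in red, the others in grey and the list median as a black bar. The medians run from -0.76 for mature single-positive T cell genes to 0.28 for S phase genes, whose members all lie above 0.

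Lists that describe the early stages changed in few members. Among progenitor genes of the first double-negative stage 2 of 17 were lower, Flt3 and Cd44, while the stem cell factor receptor gene Kit stood at -0.63 ± 0.286 (adjusted p = 0.479, edgeR). Among genes of the second stage and of T cell commitment 1 of 16 was lower, Il7r, and Gzmb, a granzyme, stood at 1.33 ± 0.319 (adjusted p = 0.0678). Of 19 genes of the third stage and of the pre-T cell receptor 0 passed by edgeR, over all genes or adjusted over the list alone. Of 20 genes of CD4 CD8 double-positive cells 2 were lower, the transcription factor Lef1 (1.62-fold) and the activation marker Cd69 (1.91-fold). None of these lists was called over all 5 libraries (camera adjusted p = 0.105, 0.732, 0.231 and 0.732), and the progenitor list was called as lower without Toxf/fPdcd1Cre replicate 1 or 3 (adjusted p = 0.0130 and 0.0390). Lef1 and Cd69 lost their calls without the library of Toxf/f replicates 1 and 2 (adjusted p = 0.264 and 0.308) or Toxf/f replicate 3 (adjusted p = 0.294 and 0.398), Lef1 also without Toxf/fPdcd1Cre replicate 2 (adjusted p = 0.0677) and Cd69 without Toxf/fPdcd1Cre replicate 3 (adjusted p = 0.0815).

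Annotated terms carried by the files were enriched mainly among the lower genes. Of 3694 terms tested, 102 were enriched among lower and 10 among higher genes by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Immune response held 39 lower genes among 205 tested, where 3.10 would be drawn by chance. Immunoglobulin production held 12 of 32, cellular response to interferon-beta 11 of 46, chemokine activity 9 of 35 and NF-kappa B signalling 21 of 116. Among higher genes, carbohydrate binding held 4 of 157 (adjusted p = 0.00485), which were the called genes Klra5, Klrb1c, Klrc2 and Klrk1. Immunoglobulin terms stood there too, each through the same pair of genes, Igll1 and Trdc. These were circulating immunoglobulin complex (2 of 16, adjusted p = 0.0160), immunoglobulin receptor binding (adjusted p = 0.0263), activation of B cells (adjusted p = 0.0304) and antigen binding (adjusted p = 0.0398). The same terms held more lower genes, in this order 6 of 16, 7 of 21, 6 of 23 and 7 of 27.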

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

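Counting the identical files as separate libraries and numbering the shared library 1 in a block were chosen after seeing the data. Tox stayed lower and past the threshold under all 17 alternatives (log2 fold change -2.94 to -2.58, adjusted p from 3.13e-50 to 0.00152). The count of 232 changed genes became 417 with no low-count filter, 67 at 10 CPM or more in 3 libraries, 125 with age as a covariate, 359 with DESeq2, 117 with limma on log2(FPKM + 1) and 380 with the identical files counted separately; leaving out single libraries gave 31 to 606. With the replicate number as a block it was 868 (all 232 among them), and 435 with the shared library numbered 1. In the former fit Toxf/fPdcd1Cre replicate 1 was alone in its block, and in the latter Toxf/fPdcd1Cre replicate 2 was. A library alone in its block adds nothing to the comparison, so each fit compared in effect 2 libraries per genotype. Whether replicate numbers pair the samples cannot be told from only 2 pairs. The correlation of deviations between same-numbered libraries was -0.0309, and -0.199 with the shared library numbered 1. The blocked calls gave 186 enriched terms against 112. The 13 called lists became 0 with an estimated correlation and 0 with fry's directional test, and 10 to 17 without single libraries. For 112 genes that the naming rule gave, 1859 alternative values were compared. Of these 1610 kept their side of the threshold, 171 lost their call, 78 gained one and 0 changed direction with a call in either fit. A change of direction with no call in either fit was counted as kept. Where a library was left out fewer samples were tested, and without either Toxf/f library the lone one was assumed to vary like the others; elsewhere the cause was not tested. The share of lower calls was 91.8%, and 94.0% to 94.6% with the other scalings. A pseudocount of 0.1 on FPKM was not run, since the files give counts. With 14245492 to 16199195 counts per library, most changes of 4-fold and about 64% of 2-fold changes were recovered in simulation. The simulation set no library apart from its group, as Toxf/fPdcd1Cre replicate 1 stood apart here, so these shares may not carry over.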

Other observations

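Some tests were chosen only after the result was seen. They covered the library with almost no chromosome Y reads, B cells of all kinds and shared reads. Tests on the natural killer gene complex and on the segments around Tox and Pdcd1 were also chosen then. The checks on control levels and on the overlap of libraries used below were added then as well. Thymic epithelial genes parted by compartment. Among 10 medullary genes, chosen once the called genes were known but before their own values were seen, 9 had fold changes below 0, with a median of -0.74, including Fezf2, a regulator of self-antigens, at -1.65 ± 0.393 (adjusted p = 0.0666, edgeR). Among 8 cortical genes 0 lay below 0, with a median of 0.19, including the thymus protease Prss16 at 0.24. The medians differed by -0.937 (one-sided permutation over genes p = 0.00086), but genes are not independent replicates, and the medullary median was -0.16 without Toxf/f replicate 3. Per library, the medullary minus the cortical median of log2(CPM + 1) was -3.69 and -2.81 in Toxf/f and -3.35, -4.89 and -4.64 in Toxf/fPdcd1Cre libraries, so the genotypes overlapped through Toxf/fPdcd1Cre replicate 1. A sort of double-negative thymocytes should remove epithelial cells, yet Prss16 averaged 964 and 1141 CPM in Toxf/f and Toxf/fPdcd1Cre libraries, so RNA of the epithelium was there in both. A lower medullary share in the Toxf/fPdcd1Cre pool may be followed up as a hypothesis, and the overlap of the libraries leaves it open.

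Of 18 listed mature T cell genes 10 were lower in Toxf/fPdcd1Cre cells, with a list call that was lost at an estimated correlation (adjusted p = 0.470). Toxf/fPdcd1Cre replicate 1, the library with almost no chromosome Y reads, does not account for this, since the list median without it was -0.944. A smaller share of mature T cells in the sorted pool may lie behind it and cannot be told apart from lower expression within cells; Cd8a at 1623 and 1826 CPM and Cd4 at 877 and 859 CPM go against libraries of double-negative cells alone. Another 18 mature T cell genes, likewise chosen outside the called genes, had a median of 0.065 (-0.066 without Toxf/fPdcd1Cre replicate 2). This lay above the bound of -0.1 set beforehand, so by that bound the prediction of a smaller share failed. Control levels were compared only after this was seen. The median control level of these genes was 150 CPM, against 53.1 CPM for the 10 lower genes. This leaves room for RNA from other cells to hide a small share. With age as a covariate the list median was -0.80, against -0.76 without it. The fall did not shrink, so age as fitted does not account for it. An effect of genotype within the cells stays untested.

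Class-switched immunoglobulin genes were nearly lost. The tables argue against fewer B cells of all kinds, since the median of 16 other B cell genes lay 6.11 log2 units above that of the class-switched genes. They also argue against reads shared among the 6 class-switched genes. The summed level of these genes was lower in every pair of libraries, with a log2 ratio of -5.83 in the closest pair. Reads shared with Ighm lay outside this sum and were not tested. Fewer plasma cells or switched B cells may contribute. The median of 8 plasma cell genes was 0.041 (-0.093 without Toxf/fPdcd1Cre replicate 1 and -0.018 without Toxf/f replicate 3). It lay above the bound of -0.1 set beforehand, so by that bound the prediction of fewer plasma cells failed. Control levels, compared only after this was seen, had a median of 23.6 CPM against 7.34 CPM for the 6 class-switched genes. At such levels the bound was wrong for so small a share. Jchain and Igkc fell with the class-switched genes, and the plasma cell share stays open.

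The 4 called Klr genes of 9 tested, Cd163l1 and Trdc were higher. Their median log2 fold change was 1.971 without Toxf/fPdcd1Cre replicate 1, the library with almost no chromosome Y reads. These genes were picked as higher in a fit that held the other Toxf/fPdcd1Cre libraries too. A high median was thus largely given in advance and cannot decide whether that library is a cause. A strain difference across the natural killer gene complex on chromosome 6 could raise neighbouring genes together: of 38 other tested genes within 2 Mb of the called Klr genes, 2 were called, Ccnd2 and Cd69, both lower (one-sided Fisher's exact test p = 0.125), which leaves it open for the Klr genes. A larger share of innate-like or gamma-delta cells may also contribute: the lists of gamma-delta, innate-like T, natural killer and innate lymphoid genes had medians of 0.13, 0.24, -0.20 and -0.18 and no call (camera adjusted p = 0.320, 0.330, 0.692 and 0.157), but their members went both ways, which leaves a change in a small subset open. Without Toxf/fPdcd1Cre replicate 1 these medians were -0.06, 0.08, -0.35 and -0.31, with the innate lymphoid list called as lower (adjusted p = 0.0196); the gamma-delta median was -0.01 without the library of Toxf/f replicates 1 and 2, and those of the innate-like and natural killer lists were 0.09 and 0.04 without Toxf/f replicate 3.

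Of 134 tested genes within 10 Mb of Tox or Pdcd1, Tox left out, 0 were called by edgeR. Thus 0% of the called genes lie there, and flanking segments of this size do not carry the calls. Elsewhere 1.65% of genes were called, so few calls were due among these genes. Both genotypes are Toxf/f by their labels, so a difference around Tox was less likely than around Pdcd1. The windows around these genes were pooled and not tested apart. Longer segments were not tested. The 5 libraries make 10 splits into 2 and 3, too few for a share under 0.05. The real split was the 1 split with at least 232 changed genes and the highest other gave 133, with Toxf/fPdcd1Cre replicates 2 and 3 against the rest. For gene lists 5 of the 10 splits, the real one included, gave at least the 13 called lists, and the highest other gave 18.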
